A study of Mus musculus with 10 samples.

How the data were processed

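RNA was sequenced from primary hepatocytes, which are liver parenchymal cells taken directly from the animal, of C57BL/6 mice aged 8 weeks. Per the labels, the cells received a lentivirus expressing either a negative control or KLF10, and each treatment had 5 libraries, 10 libraries in total. Total RNA was isolated with Trizol, and libraries were made from 1 ug of it with an Illumina TruSeq kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. The species and form of the KLF10 coding sequence in the virus are not given in the sources used here.

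Reads were aligned with HISAT2 2.0.5 to the mouse build mm10, per the submitters' processing notes. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited read count per gene is a whole number, not normalized, and lists 55968 features per library, of which 55471 carried a gene name and 497 were loci named only by a running number. These unnamed assembled loci held 0.122 to 0.312% of the counts of a library and stayed out of library sizes and tests, except in an alternative. In 27 gene symbols that had been turned into dates, the name was restored from the gene identifier. Of the 55471 identifiers, 55144 were in the reference annotation used here, and 99.5% of those had the same coordinates in it. The deposited FPKM values were fragments per kilobase of gene length, scaled to a library size that was 0.864 to 1.34 times the total count, and they were not used in any test.

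The deposited comparison table repeats the counts, and every count in it was identical to that of the library's own file. Its differences and averages were on a log10 scale per the values: limma on quantile-normalized log10 counts, with counts of 0 set to 1, gave the authors' deposited differences to within 5.894e-08. The authors' moderated t and log odds score, and their p-values and adjusted p-values, were not compared with those of this limma fit. The authors did not state this method in the sources used here.

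From the counts, genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, robust dispersion estimation and no covariate. An adjusted p under 0.05 (Benjamini-Hochberg) was taken as a call. CPM (counts per 1e6 of library size) were computed on TMM-scaled library sizes, and log2 fold changes are the libraries labelled KLF10 over negative control with their SE. Fold sizes of genes with 0 counts in a group were computed as lower bounds against a floor of 3 counts over the group, and genes with 1 to 3 counts in a group were given a ratio with its exact 95% counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Single values were compared with the exact two-sided permutation test over all 252 splits, whose smallest possible p was 0.00794.

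Gene lists, 45 in number, were written before the data were examined, as were the main test and design, the naming rule and the alternatives other than those given below as added. The 42 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The lists covered palmitoylation enzymes, Kruppel-like factors, lipid, glucose, bile acid and drug metabolism, inflammation, stress, cell cycle, matrix, hepatocyte zonation and identity, and markers of the other liver cells. Setting the members with at most 3 counts in a group to the lower end of their counting interval leaves them on the same side of the list median.

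Named genes followed a rule written beforehand. It took Klf10 and Zdhhc7, and the 10 genes per direction with the largest fold change among called genes with a mean of at least 5 CPM, no overlap between the groups and a regular symbol. It also allowed the 2 members per direction with the smallest adjusted p in a described list, and up to 3 abundant members of marker and stress lists. This gave 202 genes, of which 156 were called, and 124 are named. After the values were seen, 18 list members whose call was lost with a single library left out were left unnamed, as were uncalled members other than Klf10 and the Y-linked genes. A further 19 called genes whose call was kept are unnamed, some of them for reasons unrelated to their values. The named list members are therefore steadier than the rule alone would give. Of the named genes, 2 (Akr1b7 and Mup14) lost their call when a library was left out.

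Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, DESeq2 size factors, upper-quartile factors, library size only, no low-count filter, a mean of at least 5 CPM, the replicate number as a block, an adjusted p of 0.01, a 2-fold minimum, fry, camera with an estimated correlation, and each library left out. Added after seeing the data were a fit with the assembled loci, a fit without negative control replicate 2 and KLF10 replicate 5, and an exact permutation test of each library's mean log2 CPM over a list. The pipeline was tested on simulated counts for 13224 genes with 200 changed genes: 16% of 1.5-fold, 62% of 2-fold, 90% of 4-fold and 96% of 8-fold changes were recovered, and 8 of 140 calls were false. Members of families with near-identical copies (Mup, Serpina1, Serpina3, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gstp, Ces and Ugt genes), and genes that overlap another on either strand, have uncertain single values, because the authors' counting could split or share their reads.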

Results

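Gene expression was measured by RNA sequencing in mouse primary hepatocytes that, per the labels, carried a lentivirus expressing KLF10, a Kruppel-like zinc finger transcription factor, or a negative control. The series title places the experiment in a study of steatohepatitis in which KLF10 would activate zDHHC7, an enzyme that attaches palmitate to proteins. The comparison therefore asks which genes differ with KLF10, and whether Zdhhc7 is among them. Both groups had 5 libraries, with total counts from 15451234 to 17083613, and the totals did not differ between the groups (15910000 ± 157500 against 16260000 ± 702400, SD, n = 5, exact permutation p = 0.357). Replicates differed by more than counting noise in every pair, with a chi-square per degree of freedom of 14.5 to 129. The first principal component held 54.7% of the variance and separated the groups. The next held 11.5% and set KLF10 replicate 5 (score -50.3) apart from the other 9 libraries, which lay between -22.8 and 29.7.

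Klf10 itself was not higher in the libraries labelled KLF10. Its level was 59.7 ± 30.9 CPM in the negative control and 37.8 ± 11.2 CPM in the libraries labelled KLF10 (SD, n = 5 each), a log2 fold change of -0.66 (SE 0.38, 95% interval -1.504 to 0.184) with an adjusted p of 0.213 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The exact permutation p was 0.183, and no library labelled KLF10 exceeded 46.8 CPM while the controls ranged from 25.4 to 90.3 CPM. Klf10 (ENSMUSG00000037465) lies on the minus strand of chromosome 15 from 38291463 to 38300706 in mm10. Zdhhc7 (ENSMUSG00000031823, minus strand of chromosome 8 from 120080890 to 120101482) was 24.9-fold higher. It rose from 56.4 ± 31.1 to 1403 ± 369 CPM, a log2 fold change of 4.64 (SE 0.64, adjusted p = 0.000452 by edgeR), and the groups did not overlap (exact permutation p = 0.00794). By mean CPM it moved from rank 2417 in the controls to rank 69. Negative control replicate 2 held only 64 Zdhhc7 counts (4.44 CPM), against 61.6 to 88.3 CPM in the other controls, and the ratio of group means was 24.9 with it and 20.2 without it. Because the level of Klf10 goes against the label, directions below are those of the libraries labelled KLF10. The labels do not say whether reads of the viral sequence could be counted at the mouse gene.

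**Figure D1:**
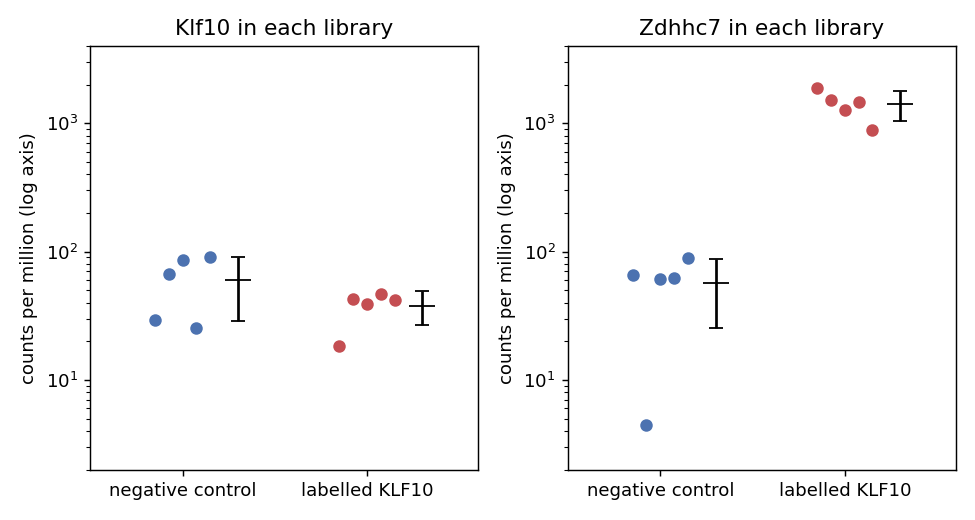
Klf10 (left) and Zdhhc7 (right) in each library, in CPM on a log axis, with the negative control in blue and the libraries labelled KLF10 in red; the bars give the mean and SD of 5 libraries. Klf10 overlaps between the groups, whereas Zdhhc7 lies between 4.44 and 88.3 CPM in the controls and between 879 and 1890 CPM in the libraries labelled KLF10.

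The libraries labelled KLF10 held far more transcript of several liver enzymes that the controls nearly lacked, and far less of secreted major urinary proteins and of the lipogenic desaturase Scd1. Of 13402 genes tested, 2197 were higher and 2026 were lower, 31.5% in total. At least 2-fold changes were found in 1037 higher and 658 lower genes, and at least 4-fold changes in 267 and 154. The groups did not overlap in 2652 genes (19.8%, against 0.794% by chance). With library size only in place of TMM factors, which shifted the median log2 fold change by 0.225, 3469 genes were higher and 1156 lower, so that 75% of the calls were higher instead of 52%. The TMM factors themselves were 0.928 ± 0.0435 in the controls and 1.08 ± 0.141 in the libraries labelled KLF10 (SD, n = 5, exact permutation p = 0.0238), with the highest, 1.32, in KLF10 replicate 5.

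Sult1e1, the estrogen sulfotransferase, rose from 0.0535 ± 0.0564 to 178 ± 66.4 CPM (log2 fold change 11.49, SE 0.43, adjusted p = 2.92e-10 by edgeR). The cytochrome P450 Cyp2b9 rose from 0.133 ± 0.0895 to 218 ± 54.8 CPM, a log2 fold change of 10.57. Vmn2r3, a vomeronasal receptor gene, had 0 counts in the controls and 70.3 ± 19.3 CPM in the libraries labelled KLF10, at least 1743-fold higher over a floor of 3 counts in the group. Cyp3a44 had 1 count in the controls and 58.3 ± 48.5 CPM in the libraries labelled KLF10, a ratio of 4283 with a counting interval of 768 to 169200; its fitted log2 fold change of 11.42 was 12.90 without negative control replicate 1 and 10.78 without KLF10 replicate 1. Gask1a, Ypel2, Ly6d and the transcriptional corepressor Nab2 rose by 7.73, 6.24, 6.02 and 5.92 on the log2 scale. Ypel2 was 4.88 without KLF10 replicate 1, and Nab2 was 6.53 without negative control replicate 3. The aldo-keto reductase Akr1b7 (log2 fold change 6.87, adjusted p = 0.0325) rested on KLF10 replicate 5, with 151 CPM against 1.68 to 3.61 CPM in the other 4. Without that library it was 3.19 (9.13-fold), and without any single control its call was lost (adjusted p = 0.0664 to 0.0748). It was lost as well by limma-voom (adjusted p = 0.213), with sample quality weights (0.0540) and without a low-count filter (0.0564).

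Among the genes that fell, the serpin Serpina1e went from 9250 ± 1916 to 43.2 ± 13.5 CPM (log2 fold change -7.74, SE 0.30, adjusted p = 2.57e-10 by edgeR), and the summed Serpina1 family fell by 0.97. Scd1, which makes monounsaturated fatty acids, fell from 8836 ± 1975 to 205 ± 217 CPM (log2 fold change -5.43, and -6.35 without KLF10 replicate 5). The major urinary protein genes Mup7, Mup3 and Mup17 fell by 5.90, 5.04 and 4.49 on the log2 scale. Because Mup copies share reads, the family was also summed: it fell from 35490 ± 5757 to 2228 ± 538 CPM, a log2 fold change of -3.99 (SE 0.23, adjusted p = 1.57e-08). Mup19 had a log2 fold change of -5.33, which was -4.74 without negative control replicate 1 and -6.11 without KLF10 replicate 2. Mup14 held 3 counts in the libraries labelled KLF10, a ratio of 5580 with a counting interval of 1909 to 27060. Its fitted value of -12.16 (adjusted p = 0.0150) was -8.34 (324-fold) without negative control replicate 5, and its call was lost without KLF10 replicate 5 (adjusted p = 0.132), by limma-voom (0.202) and with sample quality weights (0.269). The pseudogene Serpina4-ps1 went from 106 ± 41.5 CPM to 1 count, a ratio of 9307 with a counting interval of 1670 to 367700; its fitted value was -12.43, and -13.75 without KLF10 replicate 3. Sipa1l2 fell from 287 ± 156 to 0.540 ± 0.571 CPM (512-fold lower, and 877-fold without KLF10 replicate 2), and the desmosomal cadherin Dsg1c fell by 5.46.

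**Figure D2:**
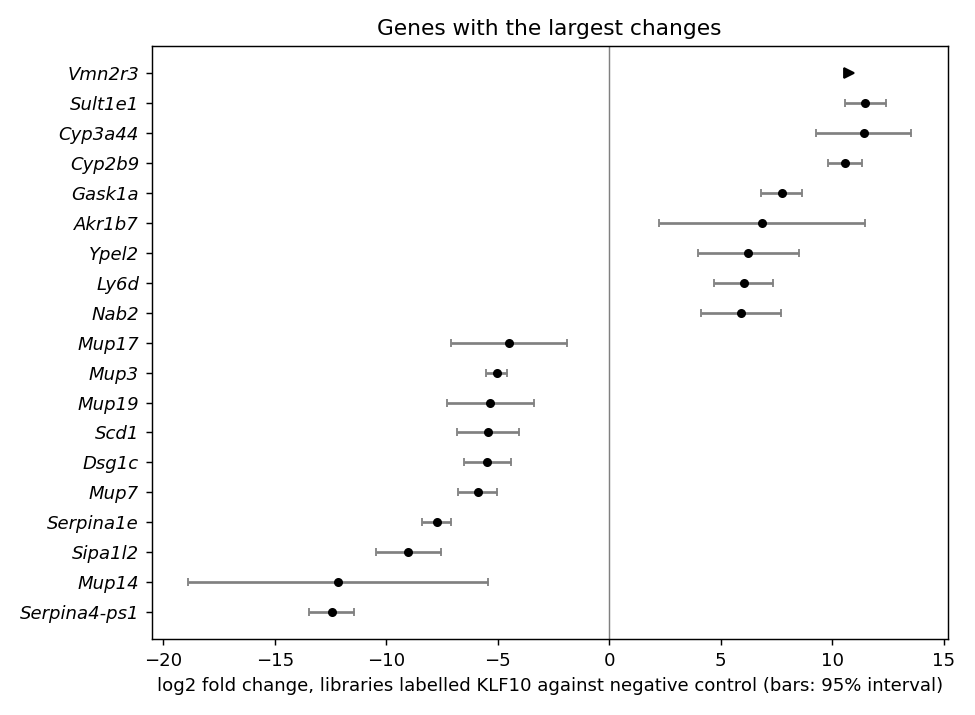
Log2 fold changes of 9 genes with the largest increases and 10 with the largest decreases, libraries labelled KLF10 against negative control, with 95% intervals as bars; the triangle gives the lower bound for Vmn2r3, which had 0 counts in the controls. Fitted values run from -12.43 for Serpina4-ps1 to 11.49 for Sult1e1, with the widest intervals for Mup14 and Akr1b7.

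Liver genes that differ between the sexes or respond to growth hormone held large changes in both directions. Of 24 tested, 7 were higher, 14 were lower and 3 were not called, with the same counts adjusted over the list alone. The higher ones included Cyp2b9, which is expressed mainly in females, and the lower ones Mup3 and Cyp4a12b, which are expressed mainly in males. Cyp4a12b fell from 76.3 ± 18.3 to 5.81 ± 1.14 CPM (log2 fold change -3.71), and Cyp4a12a fell by 3.91. The list was lower by camera (median -0.93, mean -0.0025, adjusted p = 0.0234) and not with an estimated correlation (adjusted p = 0.762 with an estimated correlation), nor without negative control replicate 2 and KLF10 replicate 5 together. The list pools genes expressed mainly in males with genes expressed mainly in females. Its direction therefore depends on how many of each were listed and is not read as a shift of the whole list. The Y-linked transcripts Kdm5d, Uty, Ddx3y and Eif2s3y had log2 fold changes of 0.19, 0.49, 0.038 and -0.041 and were not called; they were the 4 tested of the 6 sex-linked transcripts, with 0 calls adjusted over the list alone and a median of 0.11. Uty was called without KLF10 replicate 1 (0.62, adjusted p = 0.0139) and with library size only (0.77, adjusted p = 0.0317), and Eif2s3y was 0.19 with library size only.

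Among genes of the functions that hepatocytes perform in the periportal zone, in amino acid breakdown and in secretion of complement and coagulation factors, many more were lower than higher in the libraries labelled KLF10, although the lists passed camera only at its preset correlation (adjusted p = 0.762 to 0.778 with an estimated correlation). Among 24 periportal genes 17 were lower, 1 was higher and 6 were not called, with 18 lower and 1 higher adjusted over the list alone. The urate oxidase gene Uox fell from 2835 ± 257 to 786 ± 202 CPM and Mup20 from 3836 ± 355 to 728 ± 219 CPM. Of 43 genes of the urea cycle and amino acid metabolism, 25 were lower, 4 were higher and 14 were not called, with 28 lower and 5 higher adjusted over the list alone. Afmid and Haao, enzymes of tryptophan breakdown, fell by 2.44 and 1.64 on the log2 scale, whereas Bhmt, which remethylates homocysteine, rose from 1742 ± 540 to 7169 ± 1345 CPM and Dmgdh by 0.81. In the complement and coagulation list 21 of 41 genes were lower, 0 were higher and 20 were not called, with 23 lower adjusted over the list alone; C6 of the terminal pathway and C4a fell by 3.32 and 1.54 on the log2 scale. Hepatocyte identity genes numbered 37, with 12 lower, 2 higher and 23 not called, and 14 lower and 2 higher adjusted over the list alone. In this list Ahsg, which encodes the plasma protein fetuin-A, rose from 6442 ± 617 to 12970 ± 3109 CPM. Bile acid synthesis and transport had 15 lower, 5 higher and 9 uncalled genes of 29, with the same counts adjusted over the list alone. The uptake transporter gene Slco1a1 fell by 3.20 and Cyp7b1 by 2.34, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Cyp39a1 rose by 1.89 and 1.39. De novo lipogenesis had 9 lower genes, 1 higher and 17 not called of 27, with 10 lower and 2 higher adjusted over the list alone, and beside Scd1, Mid1ip1 fell by 1.55 and Acss2 from 220 ± 56.4 to 77.5 ± 14.4 CPM.

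All 6 of these lists were lower by camera at the preset correlation, with adjusted p = 2.90e-07 for periportal genes (median log2 fold change -0.98), 1.23e-06 for the urea cycle list (-0.69), 6.02e-09 for complement and coagulation (-0.60), 0.000499 for hepatocyte identity (-0.42), 0.00311 for bile acids (-0.50) and 0.00893 for lipogenesis (-0.30). None of the 6 passed camera with the correlation estimated: adjusted p = 0.762 with an estimated correlation for the periportal, complement and lipogenesis lists, 0.778 for the urea cycle and bile acid lists and 0.794 for hepatocyte identity. The share of counts from Alb, the albumin gene, was 7.92 ± 0.360% in the controls and 8.75 ± 1.10% in the libraries labelled KLF10 (SD, n = 5, exact permutation p = 0.135).

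Among genes of the extracellular matrix, interferon-stimulated genes and genes that rise when hepatocytes dedifferentiate in culture, many more were higher than lower, although the lists passed camera only at its preset correlation (adjusted p = 0.762 to 0.778 with an estimated correlation). Of 33 matrix and fibrosis genes 20 were higher, 1 was lower and 12 were not called, with 23 higher and 1 lower adjusted over the list alone. The proteoglycan genes Dcn and Lum rose from 103 ± 12.6 to 258 ± 61.8 CPM and from 5.06 ± 1.59 to 17.6 ± 7.03 CPM, and the macrophage metalloelastase Mmp12 fell by 0.76. Markers of hepatic stellate cells and fibroblasts, 5 of which are also in the matrix list, had 10 higher genes of 17, 0 lower and 7 not called, with 15 higher adjusted over the list alone; Pdgfra rose from 3.98 ± 0.562 to 13.9 ± 4.78 CPM. Beside them, markers of Kupffer cells and macrophages had a median of -0.35, with 1 higher, 2 lower (Clec4f and Timd4, by -0.85 and -1.57) and 16 not called of 19. Markers of sinusoidal endothelial cells had a median of 0.023, with 1 higher (Stab2, by 0.69), 0 lower and 17 not called of 18, and for both of these lists the counts adjusted over the list alone were the same. Clec4f was not called with library size only (adjusted p = 0.0507). The Kupffer median was 0.25 without negative control replicate 3, and the endothelial median was -0.066 without negative control replicate 2, -0.043 without replicate 5 of the control and -0.089 without KLF10 replicate 5. In the dedifferentiation list 20 of 40 genes were higher, 1 was lower and 19 were not called, with 22 higher and 1 lower adjusted over the list alone. S100a11 and Anxa2 rose by 2.60 and 2.37, and Cdh1, the epithelial cadherin, fell by 1.15.

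Interferon-stimulated genes numbered 46, with 24 higher, 2 lower and 20 not called, and 30 higher and 2 lower adjusted over the list alone; Usp18 rose from 6.19 ± 1.31 to 30.1 ± 3.45 CPM and Gbp3 by 1.88, while Bst2 fell by 0.90. In the NF-kappaB and cytokine list 10 of 25 genes were higher, 2 were lower and 13 were not called, with 11 higher and 2 lower adjusted over the list alone. The chemokine genes Cxcl10 and Ccl2 rose by 2.43 and 2.96 on the log2 scale, and Tnfaip2 fell by 1.04. Rela, an NF-kappaB subunit, fell by 0.60, and it was not called with library size only (-0.38, adjusted p = 0.0743). Cell cycle genes had 13 higher, 1 lower and 21 not called of 35, with the same counts adjusted over the list alone. Their levels were low: the proliferation marker Mki67 rose from 1.14 ± 0.343 to 6.33 ± 3.14 CPM and Ube2c from 0.447 ± 0.219 to 2.16 ± 1.15 CPM, and E2f1 fell by 1.34. Of 79 cytosolic ribosomal protein genes, 29 were higher, 1 was lower and 49 were not called, with the same counts adjusted over the list alone, and Rps12 and Rpl13a rose by 1.09 and 1.21.

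By camera at the preset correlation these 7 lists were higher, with adjusted p = 1.46e-05 for matrix genes (median 0.86), 0.000131 for stellate markers (0.79), 2.26e-05 for dedifferentiation (0.78), 2.11e-05 for interferon-stimulated genes (0.67), 0.0153 for NF-kappaB (0.58), 0.00177 for cell cycle (0.41) and 2.33e-06 for ribosomal proteins (0.38). None passed camera with inter-gene correlation estimated: adjusted p = 0.762 with an estimated correlation for stellate markers, dedifferentiation, interferon and cell cycle genes, 0.778 for matrix and NF-kappaB genes and 0.896 for ribosomal proteins. The NF-kappaB list was not called with library size only or at a mean of at least 5 CPM. In 43 of 100 splits of the 10 libraries, the real one included, camera called as many lists, and up to 25. The other splits mix the groups and keep part of their difference, so this is not a rate under chance alone. The exact permutation test of library means called 12 of the 14 camera lists, with adjusted p = 0.0238 for each except 0.0417 for the urea cycle list, and did not call ribosomal proteins (adjusted p = 0.0833) or the growth hormone list (0.121). That test also called TGF-beta response (0.0417) and, at 0.0238, glycolysis, p53 targets and immediate early genes as higher. It compares list levels, so its calls move with scaling. With library size only, it also called further lists higher, among them cholesterol synthesis, heat shock and ribosomal proteins (exact permutation adjusted p = 0.0167, 0.0167 and 0.0267). Of the 6 lower lists, 5 stayed called lower.

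**Figure D3:**
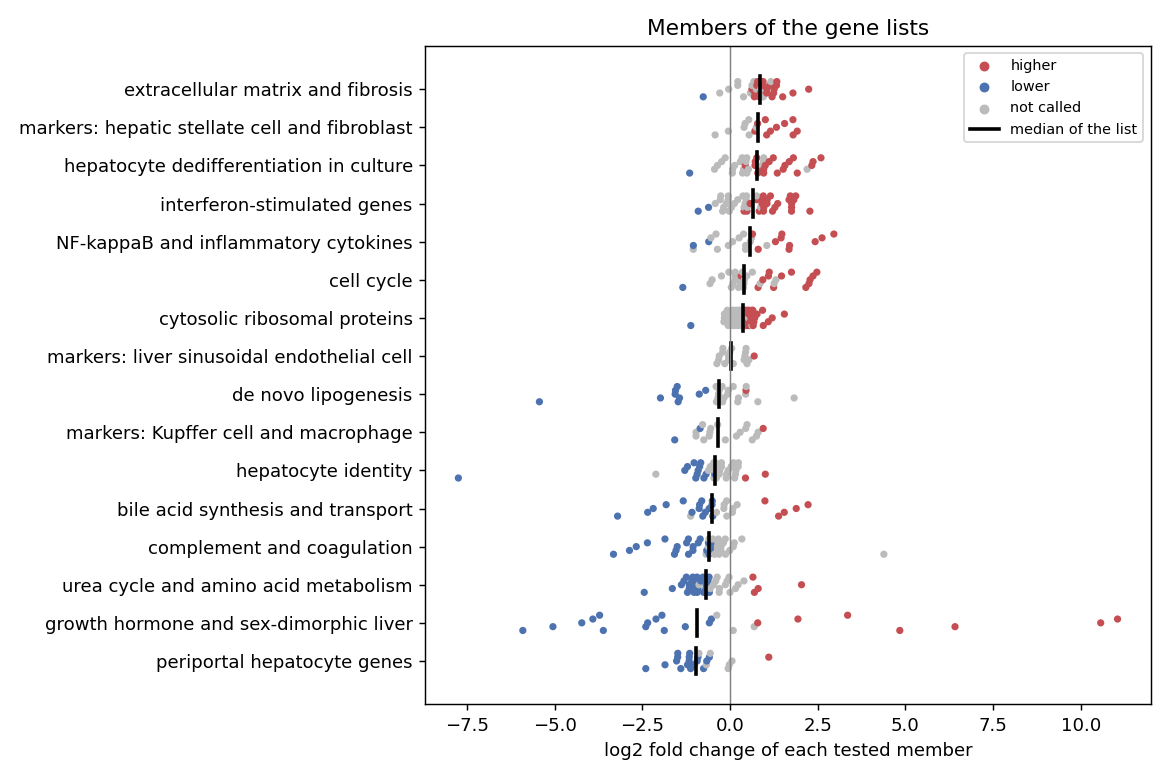
Log2 fold changes of the members of the 14 lists called by camera and of 2 further marker lists, libraries labelled KLF10 against negative control, 1 point per tested gene (red higher, blue lower, grey not called) with the list median as a black bar; height within a row only spreads the points. Medians run from -0.98 for periportal genes to 0.86 for matrix genes, and the endothelial and Kupffer marker medians are 0.023 and -0.35.

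Genes of lipid and glucose metabolism outside lipogenesis moved in both directions within each list, and no list of them passed camera. Cholesterol synthesis had 10 higher, 5 lower and 10 uncalled genes of 25 (11 higher and 7 lower adjusted over the list alone, median 0.092). Sqle and Msmo1 rose by 1.10 and 1.13, and Tm7sf2 and Ebp fell by 1.74 and 0.70. Of 28 genes of fatty acid uptake and lipid droplets, 7 were higher, 9 were lower and 12 were not called, with 9 higher and 10 lower adjusted over the list alone (median 0.14). The fatty acid transporter Cd36 rose from 32.2 ± 9.78 to 138 ± 22.9 CPM and the binding protein Fabp5 from 0.976 ± 0.586 to 38.2 ± 6.72 CPM, whereas Slc27a5 and the hepatic lipase Lipc fell by 2.19 and 1.27. Fatty acid oxidation and PPAR-alpha targets had 8 higher, 8 lower and 20 uncalled genes of 36, unchanged when adjusted over the list alone (median -0.16); Acot2 rose by 2.64 and Acaa1b fell by 1.64. Lipoprotein genes had 4 higher, 4 lower and 15 uncalled of 23, the same adjusted over the list alone (median -0.31), with the sterol transporter Abcg5 higher by 0.89 and Pltp lower (-2.49). For gluconeogenesis the counts were 6 higher, 5 lower and 13 not called of 24 (7 and 7 adjusted over the list alone, median -0.010); Igfbp1 rose from 32.3 ± 20.8 to 308 ± 96.1 CPM and Pck2 by 1.93. Glycolysis had 6 higher, 3 lower and 17 uncalled genes of 26, the same adjusted over the list alone (median 0.089), with Aldoa higher by 1.11 and Pfkm lower (-1.16).

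Drug-metabolizing enzymes held some of the largest changes in either direction. Of 39 cytochrome P450 genes, 12 were higher, 16 were lower and 11 were not called (12 and 17 adjusted over the list alone, median -0.34). Beside Cyp2b9, Cyp2c39 rose by 3.53, while Cyp2c54 fell from 260 ± 45.0 to 17.1 ± 6.03 CPM and Cyp2c67 from 386 ± 62.0 to 58.5 ± 8.40 CPM. Conjugating enzymes had 7 higher, 12 lower and 12 uncalled genes of 31, the same adjusted over the list alone (median -0.33), and Ugt2a3 and Ugt2b1 fell by 2.24 and 2.04. With library size only, camera called both lists lower (medians -0.14 and -0.12), while their library means were higher by 0.33 and 0.35 (exact permutation adjusted p = 0.0167). Pericentral hepatocyte genes had 8 higher, 6 lower and 10 uncalled of 24 (9 and 6 adjusted over the list alone, median 0.30). Lect2 rose from 105 ± 19.9 to 299 ± 38.1 CPM and the ammonium transporter Rhbg by 2.72, whereas Ces1f and Cyp27a1 fell by 2.27 and 1.33. In the NRF2 antioxidant list 5 of 31 genes were higher, 9 were lower and 17 were not called (7 and 11 adjusted over the list alone, median -0.20); Srxn1 and Gstm2 rose by 1.54 and 1.37, and Aox1 and Gstp1 fell by 1.61 and 3.17, with the summed Gstp pair at -3.17.

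Stress and signalling lists were mixed as well. Immediate early and dissociation genes had 8 higher, 3 lower and 11 uncalled of 22, the same adjusted over the list alone (median 0.53, camera adjusted p = 0.0999); Gadd45b and Gadd45g rose by 2.94 and 4.38, and Ier2 and Junb fell by 0.71 and 0.80. This list was called higher by DESeq2 and without a low-count filter, and its median was 0.0022 without KLF10 replicate 5 and 0.18 with sample quality weights. TGF-beta response genes had 7 higher, 2 lower and 18 uncalled of 27, the same adjusted over the list alone (median 0.30), and the list was called without negative control replicate 3. Ccn2 and Tgfbi rose by 2.71 and 1.01. The unfolded protein response had 11 higher, 10 lower and 15 uncalled genes of 36 (12 and 13 adjusted over the list alone, median -0.23), with Atf3 and Dnajb9 higher by 3.46 and 1.29 and Asns and Pdia6 lower (-2.57 and -0.84). Of 29 p53 targets and apoptosis genes, 8 were higher, 3 were lower and 18 were not called (9 and 4 adjusted over the list alone, median 0.050); the cell cycle inhibitor Cdkn1a rose by 2.76. Heat shock genes had 3 higher, 1 lower and 14 uncalled of 18, the same adjusted over the list alone (median 0.087). Hspb1 rose from 1.20 ± 0.718 to 53.4 ± 15.8 CPM, Hspa8 rose by 0.77, and Hsp90aa1 fell by 0.70 except with library size only (-0.47, adjusted p = 0.119). Hypoxia genes had 2 higher, 5 lower and 13 uncalled of 20 (3 and 5 adjusted over the list alone, median -0.18); Ddit4 rose by 4.89, and Epas1 fell by 0.58 except with library size only (-0.37, adjusted p = 0.0676). Acute phase genes had 5 higher, 6 lower and 18 uncalled of 29 (6 and 6 adjusted over the list alone, median 0.068). Serpina3k fell from 11740 ± 1299 to 1880 ± 503 CPM, and Hamp2, a copy of the hepcidin gene, rose by 2.86.

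Zdhhc7 had the largest change among the called palmitoyltransferases. Of 19 tested, 2 were higher, 2 were lower (Zdhhc14 and Zdhhc18, by -1.83 and -0.63) and 15 were not called, the same adjusted over the list alone (median -0.088). Depalmitoylating thioesterases had 2 higher, 0 lower and 7 uncalled of 9, the same adjusted over the list alone (median -0.0041), with Lyplal1 higher by 0.51. Kruppel-like and Sp factors had 1 higher (Klf6, by 1.80), 2 lower and 14 uncalled of 17, and 1 higher and 0 lower adjusted over the list alone (median -0.027). Circadian clock genes had 2 higher, 5 lower and 15 uncalled of 22, the same adjusted over the list alone (median -0.18), with Csnk1e higher by 1.13 and Nfil3 lower (-1.14). Nuclear genes of oxidative phosphorylation had 2 higher, 8 lower and 57 uncalled of 67, and 0 higher and 2 lower adjusted over the list alone (median -0.064); Sdha fell by 1.03. Mitochondrially encoded genes had 2 higher, 1 lower and 12 uncalled of 15, with 0 calls adjusted over the list alone (median 0.30). The ribosomal RNA mt-Rnr1 was higher by 0.98, and it was not called without negative control replicate 2 and KLF10 replicate 5 together (0.61, adjusted p = 0.0829).

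Lists of markers of further cell types were short. Cholangiocyte markers had 1 higher (Cd24a, by 1.69), 0 lower and 9 uncalled of 10, and T, NK and B lymphocyte markers 2 higher, 1 lower and 3 uncalled of 6, with Cd52 at 1.32 and Ighm at -1.32. Erythroid markers had 0 higher, 1 lower (Alas2, by -1.86) and 4 uncalled of 5, with 2 lower adjusted over the list alone. Counts adjusted over the list alone were the same for cholangiocytes and lymphocytes, and the medians of these lists were 0.42, -0.86 and -0.57. Without a low-count filter the lymphocyte median turned to 0.642. Neutrophil markers (1 higher of 3, 2 not called, 2 higher adjusted over the list alone, median 1.15) and adipocyte markers (1 higher, Cidec by 2.18, of 4, 3 not called, 1 higher adjusted over the list alone, median 2.55) had too few members for a list test. The adipocyte median was 1.27 without KLF10 replicate 5, and 2 of the uncalled adipocyte markers had an SD above their mean in the libraries labelled KLF10.

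The 28 lists that were tested and not called had camera adjusted p from 0.0999 to 0.996. The mean was above 0 and the median below 0 for palmitoyltransferases, thioesterases, Kruppel-like factors, gluconeogenesis, unfolded protein response, cytochrome P450, conjugating enzymes and hypoxia, with the test pointing down except for thioesterases, Kruppel-like factors and gluconeogenesis. For fatty acid uptake and acute phase genes, median and mean were above 0 and the test pointed down. With library size only, the medians of palmitoyltransferases, thioesterases, Kruppel-like factors, fatty acid oxidation, gluconeogenesis, unfolded protein response, NRF2, circadian, oxidative phosphorylation and hypoxia genes lay above 0. A single library turned the median for fatty acid uptake (-0.0099 without KLF10 replicate 1), acute phase (-0.36 without KLF10 replicate 1, -0.014 without negative control replicate 1), p53 targets (-0.036), oxidative phosphorylation (0.025) and erythroid markers (0.18), the last 3 without negative control replicate 1, and for oxidative phosphorylation also without KLF10 replicate 5 (0.00012). Medians of thioesterases, Kruppel-like factors and gluconeogenesis, which lay within 0.03 of 0, turned without any of several libraries. The fry test, which asks whether a list's genes move on balance to the same side, called 7 lists higher and 7 lower, and its test for change in either direction called 39.

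By the call in the authors' deposited table, 1165 features were higher and 1148 were lower. Of the calls in the authors' deposited table, 2043 were for genes tested here; 1890 were called in both, all in the same direction, 153 only there and 2333 only here. The authors' deposited table gave Zdhhc7 a log10 difference of 1.61 with an adjusted p of 0.00578 and Klf10 a difference of -0.140 with an adjusted p of 1. Of the named genes with the largest changes, Akr1b7 and Mup17 were not called in the authors' deposited table (adjusted p = 0.138 and 0.109).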

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

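Chosen only after the results were seen were the tests of the Klf10 interval, of the genes around Zdhhc7, of the Y-linked transcripts, of the markers of other liver cells and of the list levels with library size only.

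Zdhhc7 was 24.9-fold higher while Klf10 was not higher, although the label names KLF10. A construct whose reads count at mouse Klf10 at 4 or more times the control level would need a log2 fold change of at least 2, or of -2 with the group labels exchanged, and the interval of Klf10 ran from -1.5 to 0.184, so both are argued against. A change of the whole region as large as that of Zdhhc7 is argued against as well. The other 7 tested genes within 300 kb had a median of 0.0922 (median absolute deviation 1.01, highest Crispld2 at 1.46), below the lower end of the Zdhhc7 interval of 3.23. This bound was chosen after a first one, a median under 1 by more than the deviation, was not met. A smaller change shared by the region is therefore not decided. Open readings are a KLF10 sequence whose reads do not count at the mouse gene and that induced Zdhhc7, a Zdhhc7 coding sequence in the virus, and another way of inducing the gene. The level of A130014A01Rik, which starts beside the Zdhhc7 promoter (0.173, not called), does not separate them because gene counts do not tell viral from cellular transcripts.

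Of the liver genes in the first lists, 3 of 4 expressed mainly in females, such as Cyp2b9, were higher and 0 lower, and of 12 expressed mainly in males 10 were lower and 2 higher (Elovl3 and Mup11, the latter named after its value was seen). Animals of the other sex as the whole source of a library are argued against, since the lowest Y-linked median of a library labelled KLF10 was -0.237 on the log2 scale against the control mean; Xist, however, had 8 to 18 counts in the libraries labelled KLF10 and 0 to 5 in the controls, without overlap, so a small share of female cells stays open. Reads shared between Mup copies are argued against by the summed family, whose interval ended at -3.5. Whether the shift extends to sex-biased genes outside the first lists stays open: the added female-biased genes (7 higher, 5 lower and 5 not called of 17) had a median of -0.0057 and the added male-biased genes (2, 5 and 1 of 8) a median of -1.66, with a permutation p of 0.282 across genes. Lower growth hormone signalling stays open as well. Its direct targets Socs2 (0.692, interval -0.26 to 1.65) and Cish (0.095) were not called, while Ghr (-1.27), Igf1 (-0.59) and Igfals (-0.53) were lower. Igf1 and Igfals were not called with library size only (-0.35 and -0.32, edgeR adjusted p = 0.102 and 0.0554). Bcl6 was also lower (-1.87) and is not counted for or against, since the direction in which growth hormone moves it was not examined. Igfals and Bcl6 were named after their values were seen.

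By camera at the preset correlation, the periportal, urea cycle, complement, hepatocyte identity, bile acid and lipogenesis lists were lower and the matrix and stellate lists higher. Cytochrome P450, conjugation, lipoprotein, fatty acid oxidation, acute phase and gluconeogenesis lists were not called (camera adjusted p = 0.136 to 0.996). No list passed camera with an estimated correlation (lowest adjusted p = 0.762). A lower share of hepatocytes with stellate, Kupffer and endothelial markers raised alike is argued against. Markers of cholangiocytes, lymphocytes, neutrophils, erythroid cells and adipocytes were not part of this comparison. The stellate median was 0.79, against -0.35 for Kupffer cells and 0.023 for endothelial cells. By library means, stellate markers were higher (exact permutation adjusted p = 0.0238), and Kupffer and endothelial markers were not called (0.658 and 0.825). The permutation p across genes was 1e-05, the smallest that the permutations can give. It treats genes as independent, although their estimated correlations were 0.433, 0.65 and 0.627, and does not measure the spread between libraries. A change in the number or state of stellate cells or fibroblasts, also one that lowers the hepatocyte share, stays open. KLF10 replicate 5, which stood apart, is argued against as the cause, since 100% of the 14 list calls at the preset correlation were kept without it. The TMM factors are argued against as the whole cause of the lower lists, since 5 of the 6 lower lists that the exact permutation test of library means called (83.3%) stayed lower by it with library size only, all but lipogenesis (-0.38, exact permutation adjusted p = 0.0595). The pericentral hepatocyte list (8 higher and 6 lower of 24, median 0.30, camera adjusted p = 0.656) and the share of Alb (7.92 and 8.75%) were not lower, and no biological explanation was tested.

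Chance in how the 10 libraries fall into groups is argued against for the number of genes. Of 100 splits 1, the real one, called 4223 genes, and the highest other split called 1100. The other splits mix the groups, so a group difference adds to their spread and lowers their calls. The splits treat libraries as independent, which the labels do not settle, so chance between animals or cultures was not tested. For the number of lists by camera at the preset correlation, chance could not be excluded. There, 43 of 100 splits called at least the real 14 lists, and the highest other split called 25. The other splits held 3 or 4 libraries of 1 label on a side and so kept part of the group difference. That part can itself give list calls, so 43 of 100 is not a rate under chance alone. The splits therefore do not decide the question for the lists.

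Single libraries far from the other 4 of their group were found in 24 of 275 checks, against about 13.8 by chance, since chance gives about 1 in 20. KLF10 replicate 5 had the lowest Cyp2b9 (127 CPM, others 215 to 265), Acss2 (52.4), Lipc (40.6), Pltp (3.08), Cyp27a1 (130), Haao (132), Dmgdh (443) and Ces2a (29.0 CPM, others 51.9 to 60.2), the highest Akr1b7 (151) and the highest share of assembled loci (0.1993%, others 0.122 to 0.131%). KLF10 replicate 1 had the lowest Klf10 (18.4, others 39.0 to 46.8) and Kdm5d (11.5) and the highest Acot2 (44.9) and Ube2c (4.19), and KLF10 replicate 3 the lowest Clec4f (17.8). Negative control replicate 1 had the highest Mup19 (41.6), Mki67 (1.74) and Lrfn3 (79.8, others 69.5 to 71.8), and negative control replicate 2 the lowest Zdhhc7 (4.44) and Gadd45b (1.32). Negative control replicate 3 had the lowest Ebp (176), Gstm2 (41.1), number of genes detected (18253, others 19148 to 19281) and lncRNA share (0.3071%, others 0.374 to 0.395%).

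The assembled loci, which stayed out of the main tests, also carried a signal: of 225 tested, 54 were higher and 34 lower. One on chromosome 12 from 19117210 to 19122636 went from 19.4 ± 16.8 to 247 ± 235 CPM (log2 fold change 3.42, edgeR adjusted p = 0.0170), and one on a patch scaffold from 61226725 to 61402323 from 730 ± 679 to 0.306 ± 0.586 CPM (log2 fold change -11.31, edgeR adjusted p = 0.000256). The range on the patch includes the positions of Mup14 on chromosome 4 (61300023 to 61304000). The chromosome of the patch was not examined, so it is open whether this signal is separate from that of the Mup genes.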

How the results depend on the processing

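Added after seeing the data were the fit with the assembled loci, the fit without negative control replicate 2 and KLF10 replicate 5, and the exact permutation test of lists. Against 2197 genes higher and 2026 lower, counts moved by over 1.5 times with library size only (3469 and 1156), at an adjusted p of 0.01 (1133 and 1162), with a 2-fold minimum (1037 and 658) and in the authors' deposited table (1165 and 1148). With library size only the cause was the shift of 0.225 log2, at 0.01 and 2-fold the stricter limit; for the authors' deposited table the cause was not tested. The other settings stayed within 1.5 times: DESeq2 gave 2399 and 2327, limma-voom 2039 and 2010, sample quality weights 2631 and 2483, no filter 2022 and 2039, and leaving out one library 1738 to 2594 higher and 1661 to 2348 lower. Camera with an estimated correlation called 0 lists higher and 0 lower against 7 and 7; fry called 14 lists, and the exact permutation test 16 (20 unadjusted), 12 of them among the 14. Camera compares a list with the other genes of a library, so scaling moves it little. The exact permutation test compares list levels, so its calls move with scaling. With library size only it no longer called lipogenesis and called ribosomal proteins higher (exact permutation adjusted p = 0.0595 and 0.0267). By camera at the preset correlation, other settings kept 13 or 14 of the 14 list calls, 13 with library size only, at 5 CPM and without both doubted libraries. Klf10 stayed uncalled at -0.86 to -0.31, and Zdhhc7 called at 4.33 to 5.14. Values of uncalled genes near 0 changed sign, and the cause was not tested: Eif2s3y (-0.041) was 0.0048 with upper-quartile factors, 0.19 with library size only, 0.012 at 5 CPM, 0.0016 without both doubted libraries and -0.10 to 0.011 leaving out one library; Ddx3y (0.038) was -0.012 with no filter and -0.074 to 0.11 leaving out one library; Cish (0.095) was -0.21 to 0.94 leaving out one library. Over named genes and settings, 2769 of 2802 values kept direction and side of the threshold, 18 lost and 2 gained a call and 13 changed sign. The named genes were chosen in part by this outcome. Of 20 called genes of the naming rule that lost their call without a single library, 18 had been left unnamed. The share kept is therefore higher by selection and does not measure the stability of all genes of the rule.

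With the replicate number as a block, 1657 genes were higher and 1643 lower, 3250 of them shared with the fit without it, and 7 and 7 lists were called. Libraries with the same number correlated from -0.234 to 0.0499 in their deviations from the group means, and 1 of 5 correlated best with its own number, so the numbers were not taken as pairs. Alternatives chosen beforehand for normalized values and transcripts were not run, because the files hold gene counts. At this depth and spread the self-test recovered 16% of 1.5-fold changes, with 200 changed genes among 13224. In the data 4223 of 13402 genes were called, which makes the Benjamini-Hochberg limit on the unadjusted p less strict than in the simulation. The recovery rates therefore do not carry over to the data. Changes of 1.5-fold can go uncalled, but their share was not measured.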

Other observations

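Chosen only after the values were seen were the tests of gene families by the stem of their symbol and the genes named in this part. Several families of liver enzymes held many lower genes in the libraries labelled KLF10, and the cytochrome P450 genes many in both directions. Of 215 symbol families with at least 8 tested members, 5 held more lower genes and 3 more higher genes than the background of 15.1% lower and 16.4% higher (Fisher's exact test, 430 tests, Benjamini-Hochberg, treating genes as independent). Hydroxysteroid dehydrogenases (Hsd) had 10 lower genes and 1 higher of 12 (adjusted p = 4.31e-05), and carboxylesterases (Ces) 9 lower and 3 higher of 14 (adjusted p = 0.00423). Cytochrome P450 genes (Cyp) had 30 lower and 17 higher of 69, Mup genes 13 lower and 1 higher of 17, and glucuronosyltransferases (Ugt) 9 lower and 0 higher of 17 (adjusted p = 5.85e-06, 5.85e-06 and 0.0190), although camera called neither the P450 list nor that of conjugating enzymes (adjusted p = 0.258 and 0.136). Ces2a fell from 651 ± 73.6 to 50.1 ± 12.3 CPM and Ces3b by 3.51 on the log2 scale, and the steroid enzymes Hsd3b5 and Hsd17b6 fell by 4.22 and 1.49. Hosts of small nucleolar RNAs (Snhg) and interferon-inducible Ifi genes each had 8 higher and 0 lower of 13 (adjusted p = 0.0190), and collagens 11 higher and 4 lower of 24 (adjusted p = 0.0373); Snhg18 rose from 1.09 to 3.68 CPM. With library size only, 8 Hsd and 9 Ces genes were lower and 10 Snhg genes were higher.

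Egfr, the epidermal growth factor receptor gene, fell from 798 ± 196 to 86.5 ± 36.9 CPM (edgeR adjusted p = 1.05e-06), and Lrfn3, a gene of synaptic adhesion, rose from 72.4 ± 4.22 to 1275 ± 448 CPM (edgeR adjusted p = 1.04e-08). Elovl3, which is expressed mainly in males, rose by 4.84, against the direction of the Mup genes. The share of counts in long noncoding RNA was 0.371 ± 0.0368% in the controls and 0.618 ± 0.0915% in the libraries labelled KLF10 (SD, n = 5, exact permutation p = 0.00794), and 120 of 657 tested ones were higher and 88 lower. Over all tested genes, 2197 of 13402 were higher (16.4%) and 2026 lower (15.1%). Whether the calls of long noncoding RNA differ from this background was not tested. Genes detected numbered 19020 ± 435 and 20060 ± 608 (exact permutation p = 0.0238), and mitochondrially encoded counts were 6.49 ± 1.43% and 8.47 ± 1.94% (exact permutation p = 0.135).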
